A study of Homo sapiens with 6 samples.

How the data were processed

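Tumours of the human pancreatic carcinoma line MIA PaCa-2 were grown in athymic mice from transplanted tumour pieces, and treatment began at about 100 mm3, per the labels' protocols. The labels give 3 tumours each from mice given saline and from mice given DBDx by mouth, from 3 mice per group; DBDx is dosed at 242 mg/kg. Total RNA was amplified, labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels' protocols and the file headers. Groups and replicate numbers were taken from the sample titles.

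The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes; its gProcessedSignal is an intensity after background subtraction, per the file headers, and is not normalised between arrays. Flags for saturation, non-uniform or outlying spots and signal well above background came from the same files. The authors also deposited a value table of the same arrays on a log2 scale. Its columns have the same median (6.08) and quartiles (3.75 and 8.85) on every array, as after quantile normalization, and correlate at 0.997 or more with the log2 signal of their own array. The sources used here do not name its normalization, and it was used only as an alternative. No column of that table belongs to a sample outside the series.

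An array held 44495 spots, 1377 of them controls, which were left out. The log2 of gProcessedSignal was scaled by subtracting its 75th percentile over the other 43118 spots of the array. Spots with an outlier flag were left out and spots of one probe averaged, which gave 34127 probes. The files give accessions without gene names. Of the probes, 25771 were named by matching the accession, without its version, to a RefSeq table of the GRCh38.p14 assembly, and 8356 kept the accession or probe name of the file. The array headers name another genome build, so no coordinates are given. A probe was kept if it was well above background on at least 3 of the 6 arrays, whatever their group, which left 23668 probes. The brightest probe stood for a gene, which left 19433 genes, 14966 of them with a symbol.

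Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are DBDx against saline on the log2 scale, with the moderated standard error. Gene lists, 38 in number, were written before the data were examined; 36 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. camera was also run with a correlation estimated per list, and fry as an alternative. Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among genes with a symbol, past the threshold and without overlap between the groups; 2 to 4 members with the smallest p from each list described; and a set of genes fixed beforehand, of which FKBP5, TSC22D3, ANPEP, SLC29A1, PDE5A, LTA4H, HMGCS1, VEGFA, MKI67, CDKN1A and MYC are reported. Not every gene or list that this rule covers is reported. Genes named outside this rule, in the closing observations, were chosen after their values were seen. Slides were inferred from a scan identifier that arrays share in the file headers; as the barcodes are empty, this could not be checked otherwise. With slide as a block, the group difference is estimated from slide 1, which holds 1 DBDx array.

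The steps were tested on simulated data. For DBDx against saline, with 200 of 19433 genes changed and no slide effect, the comparison recovered 62% of genes changed by 1 on the log2 scale and 92% of those changed by 2, with 3 false calls among 157; with slide as a block these shares were 8% and 71%. With a slide effect added, 11 of 144 calls were false without the block and 4 of 88 with it. For the lists, camera recovered 3 of 3 lists shifted by 0.5 and called no other of the 36. The simulated arrays varied independently, unlike the saline arrays, and so did the simulated genes. In the data the estimated correlation within a list reached 0.574 for immediate early genes and 0.808 for cytosolic ribosomal proteins. The simulation therefore cannot show false list calls that come from correlated genes.

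Alternatives were other normalizations (quantile, median scaling, normexp with an offset of 50 followed by quantile, the deposited values), no filter or a filter on all 6 arrays, the mean of a gene's probes or every probe, an intensity trend with robust variance, array weights, a replicate block, a slide block, host markers as a covariate, other thresholds, and each array left out. normexp used gMedianSignal in place of the mean signal, which the files lack. The alternatives added after seeing the data were the slide block with saline replicate 3 left out, the slide 1 arrays only, and genes with a symbol only. The weight given to leaving out saline replicate 3 was also decided after seeing the data.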

Results

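Gene expression was measured in subcutaneous tumours of MIA PaCa-2, a human pancreatic carcinoma cell line, grown in athymic nude mice. Mice received saline or DBDx by mouth, the latter at 242 mg/kg, once daily on 5 days a week for 3 weeks, and tumours were taken 3 days after the last dose. The labels give DBDx only as a code name; it is known as an oral combination of dipyridamole, ubenimex (bestatin) and dexamethasone. Each group held 3 tumours from 3 mice, and each tumour was hybridised to 1 single-colour Agilent array of human probes, so the number of arrays limits the precision. Between 64.7% and 73.6% of 34127 probes were well above background on an array, no spot was saturated, and the 75th percentile of the signal lay between 407 and 525 on the saline arrays and between 643 and 705 on the DBDx arrays. After scaling to that percentile, 19433 genes were tested. The comparison asks which transcripts of the tumour differ after the 3-week treatment.

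The MHC class II genes HLA-DPB1, HLA-DQB1 and HLA-DRB1 were among the transcripts that fell most in DBDx tumours, and HSPA6 and the laminin genes LAMA3 and LAMA4 were among those that rose most. With limma and Benjamini-Hochberg adjustment, 255 genes passed an adjusted p of 0.05, 151 of them higher and 104 lower with DBDx, and 128 of the 255 differed by at least 2-fold. The largest falls were in HLA-DPB1 (11.8-fold lower, log2 change -3.56 ± 0.45 SE, adjusted p = 0.0322), HLA-DQB1 (9.94-fold, adjusted p = 0.0235), HLA-DRB1 (7.76-fold, adjusted p = 0.0253) and CD74, the invariant chain of MHC class II (7.61-fold, log2 change -2.93 ± 0.31, adjusted p = 0.0235). MNDA, a nuclear protein of myeloid cells, was well above background in all 3 saline tumours and in none of the DBDx tumours, at least 4.76-fold lower (adjusted p = 0.0383). The imprinted zinc finger gene PEG3 fell by 2.55 on the log2 scale (5.88-fold, adjusted p = 0.0493), and MS4A8, TSPYL5, MAS1 and BCL11B fell by between 6.09-fold and 6.50-fold. The 2 kept probes of HLA-DPB1 ranged from -3.56 to -2.79, the 4 of HLA-DQB1 from -3.31 to 0.27 and the 2 of BCL11B from -2.61 to 0.48 on the log2 scale; the brightest was used. Related HLA genes can bind each other's probes, so the split between them is uncertain. In saline replicates 1 and 2 the signals were 1.87 and 0.01 (log2) for HLA-DPB1, and 4.93 and 3.59 for PEG3. HLA-DQB1, HLA-DRB1, CD74, MS4A8, TSPYL5 and MAS1 were likewise higher in saline replicate 1, so these falls may not be separate observations. MNDA (-3.37 and -2.98) and BCL11B (-1.01 and -1.20) did not share this gap.

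Among the rises, HSPA6, an inducible heat shock protein, was 6.29-fold higher with DBDx (log2 change 2.65 ± 0.16 SE, adjusted p = 0.00874; its 2 probes ranged from 1.96 to 2.65). LAMA3 and LAMA4, laminin alpha chains of the basement membrane, were 4.19-fold (adjusted p = 0.0235) and 3.58-fold higher (adjusted p = 0.0279), and the 4 kept probes of LAMA4 ranged from 0.87 to 1.84 on the log2 scale. HOXB9, a homeobox transcription factor, was at least 4.68-fold higher (adjusted p = 0.0235), and ABLIM3, an actin-binding protein, at least 4.11-fold (adjusted p = 0.0176). For SLC45A2, RASL11A, SCARNA2, KRT6C and RND3 the bounds were at least 2.29-fold, 1.83-fold, 1.60-fold, 1.28-fold and 1.04-fold, with adjusted p between 0.0187 and 0.0460. These 7 genes were well above background on all 3 DBDx arrays and on no saline array. That flag is set before scaling, and more probes had it on the DBDx arrays (69.8% to 73.6%) than on the saline arrays (64.7% to 68.2%). The pattern of flags alone therefore does not show a change. A bound sets the bright group's mean against the lowest signal well above background on each array of the dim group, or the dim probe's own where that was higher.

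The groups did not overlap in any of the 255 genes, which were picked for a group difference, so this is no separate evidence. Of all genes tested, 26.9% did not overlap. Chance gives 10% for 3 against 3 only if the 6 arrays vary independently. Saline replicate 3 mostly lay between the other saline arrays, and slide differed between the groups. The 10% is therefore no fair reference, and no conclusion is drawn from the 26.9%. Slide 1 held the 3 saline arrays and DBDx replicate 1, and slide 2 held DBDx replicates 2 and 3. With slide as a block, 60 genes passed, 11 higher and 49 lower, of which 18 were among the 255; the estimate is then the difference inside slide 1. Slide 2 held 1 group only and gives no comparison of its own. Slide block results, for genes and for lists, thus rest on 1 DBDx tumour. Across all genes tested, the difference from saline in DBDx replicate 1 correlated at 0.439 with that in DBDx replicates 2 and 3. Both differences subtract the same saline mean, which by itself raises the correlation, so 0.439 does not measure agreement between the slides. In the block model 818 genes passed for the difference of DBDx replicates 2 and 3 from DBDx replicate 1, which mixes the slide with differences between tumours. Inside slide 1 the log2 differences of HLA-DRB1, CD74, HSPA6, LAMA3 and FKBP5 were -3.26, -2.90, 2.64, 2.20 and 1.30, of which only that of HSPA6 passed with the block (adjusted p = 0.0370). Genes and lists were called with DBDx replicate 1 and the same saline arrays included. Differences inside slide 1 are therefore no separate check on the calls. The number of calls also changed when 1 array was left out. Then 76 genes passed without saline replicate 1, 24 without saline replicate 2 and 0 without saline replicate 3. Of the DBDx arrays, leaving out replicate 1 gave 1634 genes, replicate 2 gave 4 and replicate 3 gave 0. Without DBDx replicate 1 all saline arrays are on slide 1 and all DBDx arrays on slide 2. Slide and treatment cannot be told apart in that setting, for genes or for lists. Folds correlated with those from all arrays at 0.958 to 0.985, which is largely built in, as the fits share all arrays but 1. A lost call may also reflect lost power, which this correlation does not test. At the counts of 0, limma gave 2106 and 2898 genes at an unadjusted p under 0.05, against 3907 with all arrays.

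The 3 saline arrays did not vary independently. Of 3743 genes more than 0.5 apart (log2) in saline replicates 1 and 2, saline replicate 3 lay between them in 86.7%. Adding 0.39 of the signal of replicate 1 and 0.61 of that of replicate 2 left a median absolute deviation of 0.0437 (log2) in 11675 brighter genes, where spots of one probe on 1 array varied by 0.0471 (SD). For the DBDx arrays the like deviation was between 0.141 and 0.189. No gene passed with limma without saline replicate 3 (smallest adjusted p = 0.110). The folds of the called genes stayed the same size (median ratio 0.999). Adjusted p values given for single genes here are from all 6 arrays.

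**Figure D1:**
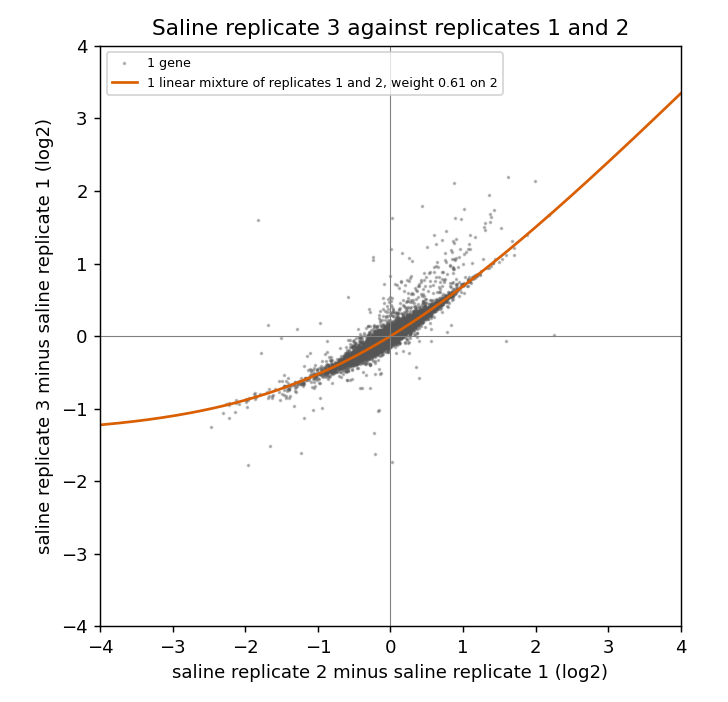
Difference of saline replicate 3 from saline replicate 1 (vertical axis, log2) against that of saline replicate 2 from replicate 1 (horizontal axis, log2), 1 point per gene for 11675 genes, of which 5 lie outside the axes. The line is 1 linear mixture with a weight of 0.61 on replicate 2. Among all genes tested, dimmer ones included, 3743 were more than 0.5 apart in replicates 1 and 2, and 86.7% of these had replicate 3 between them. Of the 11675 brighter genes, 1444 were that far apart.

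The hypoxia response list was up as a set with limma's camera at a preset correlation of 0.01 (adjusted p = 1.3e-16), but not with an estimated correlation (adjusted p = 0.242). Of 20 tested members 8 rose and none fell, and 17 rose when adjusted over the list alone; all 20 had positive estimates, with a median log2 change of 0.72. HK2, the hexokinase of the first step of glycolysis, was 2.43-fold higher (log2 change 1.28 ± 0.08 SE, adjusted p = 0.00874), with 3.02 for its other probe. INSIG2, a regulator of sterol synthesis, was 2.49-fold higher (adjusted p = 0.0113), the lipoprotein lipase inhibitor ANGPTL4 2.18-fold (adjusted p = 0.0135) and ANKRD37 2.18-fold (adjusted p = 0.0158). VEGFA, the main angiogenic growth factor, was 1.64-fold higher (log2 change 0.71 ± 0.10, adjusted p = 0.0374), with 1.43 for its other probe. Inside slide 1 the median of the list was 0.74, and with slide as a block it passed (adjusted p = 2.22e-15).

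Glycolysis genes were up as a set, with 2 of 19 members higher and none lower, or 6 higher and 1 lower when adjusted over the list alone (median log2 change 0.25, camera adjusted p = 3.87e-05, but adjusted p = 0.408 with an estimated correlation). The 2 were HK2 and SLC2A3, a glucose transporter that was 2.78-fold higher (adjusted p = 0.0253; log2 changes of its 2 probes 1.47 and 2.08). ENO2 (log2 change 0.85) and LDHB (-1.52) did not pass over all genes, at adjusted p of 0.0804 and 0.0871. With slide as a block the set passed (adjusted p = 0.000111, median inside slide 1 of 0.28). Oxidative phosphorylation genes were shifted up by a smaller amount (median 0.14, camera adjusted p = 0.0105, and adjusted p = 0.648 with an estimated correlation). None of its 22 members passed, over all genes or adjusted over the list alone, and the slide block gave an adjusted p of 0.00865 with a median inside slide 1 of 0.14. The set lost its call without saline replicate 1 (adjusted p = 0.139), without DBDx replicate 1 (adjusted p = 0.108) and with array weights (adjusted p = 0.0615).

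Metallothioneins, small proteins that bind zinc and copper and are induced by metals and glucocorticoids, rose in 5 of 9 tested members, and in 9 of 9 when adjusted over the list alone. The median log2 change was 0.74 and the camera adjusted p = 3.13e-10, but adjusted p = 0.242 with an estimated correlation. MT1X was 1.77-fold higher (log2 change 0.82 ± 0.08 SE, 1.55 for its other probe, adjusted p = 0.0235), and MT1B, MT1E and MT1H were 1.85-fold, 1.70-fold and 1.67-fold higher at the same adjusted p. These genes are near-identical in sequence, so their probes can share signal and are not 9 separate measurements. Inside slide 1 the median was 0.69, and the slide block gave an adjusted p of 2.19e-09.

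Of 18 glucocorticoid receptor targets, 2 rose and none fell, or 4 and none when adjusted over the list alone. FKBP5, a co-chaperone of the glucocorticoid receptor that the receptor itself induces, was 2.43-fold higher (log2 change 1.28 ± 0.09 SE, adjusted p = 0.0153), and ANGPTL4, which is also in the hypoxia list, was the other. TSC22D3, which encodes the glucocorticoid-induced leucine zipper, did not pass (log2 change 0.22 ± 0.12, adjusted p = 0.334). As a set the list was up (median log2 change 0.19, camera adjusted p = 0.0326), and it was not past the threshold with an estimated correlation (adjusted p = 0.584). The slide block gave an adjusted p of 0.0458 and a median inside slide 1 of 0.14, and the call ended without saline replicate 1 (adjusted p = 0.575), without DBDx replicate 1 (adjusted p = 0.0995), without DBDx replicate 3 (adjusted p = 0.0535) and with array weights (adjusted p = 0.0685).

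**Figure D2:**
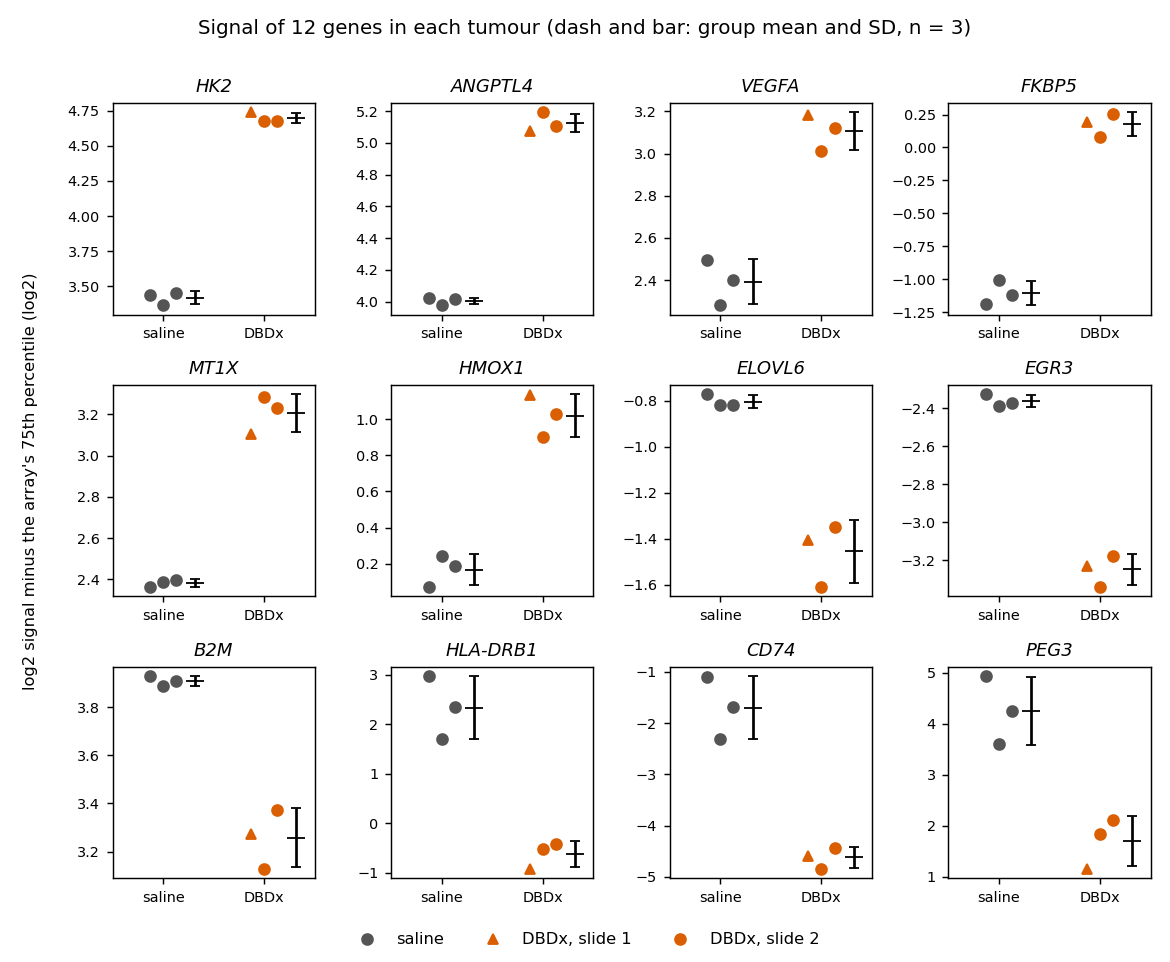
Normalised signal (vertical axes, log2 relative to the 75th percentile of the array) of 12 genes in each tumour, with the mean and SD of each group (n = 3) beside the points; triangles mark DBDx replicate 1, the DBDx array on slide 1. The 12 genes were picked from those past the threshold, in all of which the groups do not overlap.

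Lipid synthesis genes were shifted down. Of 13 fatty acid synthesis genes 1 fell and none rose, or 2 and none when adjusted over the list alone, and all 13 estimates were negative (median log2 change -0.28, camera adjusted p = 0.000181, but adjusted p = 0.242 with an estimated correlation). The gene past the threshold was ELOVL6, an elongase of long-chain fatty acids, which was 1.57-fold lower (log2 change -0.65 ± 0.10 SE, adjusted p = 0.0455). ACACA, the acetyl-CoA carboxylase, did not pass over all genes (log2 change -0.37, adjusted p = 0.121), and its 2 probes ranged from -0.37 to 0.16. None of 22 cholesterol synthesis and SREBP2 target genes passed over all genes, while 5 fell and 1 rose when adjusted over the list alone (median -0.22, camera adjusted p = 3.87e-05, but adjusted p = 0.648 with an estimated correlation). HMGCS1, the HMG-CoA synthase, had a log2 change of -0.74 ± 0.13 (adjusted p = 0.0653). With slide as a block both the fatty acid and the cholesterol list passed (adjusted p = 0.00794 and 0.00462, medians inside slide 1 of -0.28 and -0.29).

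Immediate early genes, which respond within minutes to growth factors, were down as a set (2 of 20 lower and none higher, 4 lower and none higher when adjusted over the list alone, median log2 change -0.35, camera adjusted p = 0.000745, but adjusted p = 0.728 with an estimated correlation). EGR3 was 1.85-fold lower (log2 change -0.89 ± 0.08 SE, adjusted p = 0.0200) and IER5 1.55-fold lower (adjusted p = 0.0412). The epithelial-mesenchymal transition list was also down (2 of 18 lower and none higher, 4 and none when adjusted over the list alone, median -0.22, camera adjusted p = 0.00819, but adjusted p = 0.242 with an estimated correlation). The list holds both epithelial and mesenchymal genes, so its fall does not give the direction of a transition. Its members past the threshold were the matrix glycoprotein SPARC (1.47-fold lower, adjusted p = 0.0458) and the transcription factor ZEB2 (2.27-fold lower, adjusted p = 0.0484), both mesenchymal genes. The epithelial adhesion gene EPCAM, in the same list, was well above background on all 3 saline arrays and on no DBDx array, at least 2.54-fold lower, and did not pass (adjusted p = 0.0747). With slide as a block both lists passed (adjusted p = 0.0181 and 0.00976), and their medians inside slide 1 were -0.32 and -0.19.

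The other 4 lists past the threshold each had an adjusted p between 0.0326 and 0.0333 with camera, and adjusted p between 0.392 and 0.648 with an estimated correlation. ATF4 targets of the amino acid response were up, with DDIT4, an inhibitor of mTORC1 signalling, 1.94-fold higher (adjusted p = 0.0235) and the only 1 of 19 past the threshold (3 higher and none lower when adjusted over the list alone). NRF2 targets were up, with 2 of 18 higher (3 higher and none lower when adjusted over the list alone): HMOX1, the haem oxygenase, was 1.81-fold higher (adjusted p = 0.0272) and GCLC, of glutathione synthesis, 1.72-fold higher (adjusted p = 0.0460). MHC class I genes were down, with B2M, the light chain of MHC class I, 1.57-fold lower (adjusted p = 0.0412) and the only 1 of 15 past the threshold (2 lower and none higher when adjusted over the list alone). Wnt and TGF-beta targets were down, although the Wnt antagonist DKK1 was 2.33-fold higher (adjusted p = 0.0295) while ID2 was 1.78-fold lower (adjusted p = 0.0401), and 1 rose and 7 fell of 16 when adjusted over the list alone. The medians of these 4 lists, in this order, were 0.21, 0.19, -0.11 and -0.27, and inside slide 1 they were 0.23, 0.07, -0.20 and -0.25. The slide block ended the calls of the NRF2 targets (adjusted p = 0.109) and of the Wnt and TGF-beta targets (adjusted p = 0.259), and kept the ATF4 and MHC class I lists (adjusted p = 0.0195 and 0.00794). Without DBDx replicate 1, where slide and treatment coincide, all 4 lost their call, at adjusted p of 0.303, 0.096, 0.315 and 0.0975. The ATF4 and NRF2 lists also lost it without saline replicate 1 (0.249 and 0.230) and without DBDx replicate 3 (0.104 and 0.106), the MHC class I list without saline replicate 2 (0.131) and without saline replicate 3 (0.0564), and the Wnt and TGF-beta list without saline replicate 2 (0.0566) and without DBDx replicate 2 (0.0977). Median scaling ended the calls of the ATF4, MHC class I and Wnt lists (adjusted p = 0.0518, 0.0638 and 0.0509), and the deposited values those of the ATF4 and MHC class I lists (0.0507 and 0.068). Quantile normalization (0.0535) and a replicate block (0.0697) ended the MHC class I call, and leaving out the filter ended the MHC class I and Wnt calls (0.179 and 0.663). Array weights ended all 4 (0.0658, 0.0514, 0.0571 and 0.0571).

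In all, 13 of 36 lists tested passed with camera, 7 up and 6 down, and none did with an estimated correlation. Without saline replicate 3, 12 of the 13 passed, the MHC class I list being the exception (adjusted p = 0.0564).

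**Figure D3:**
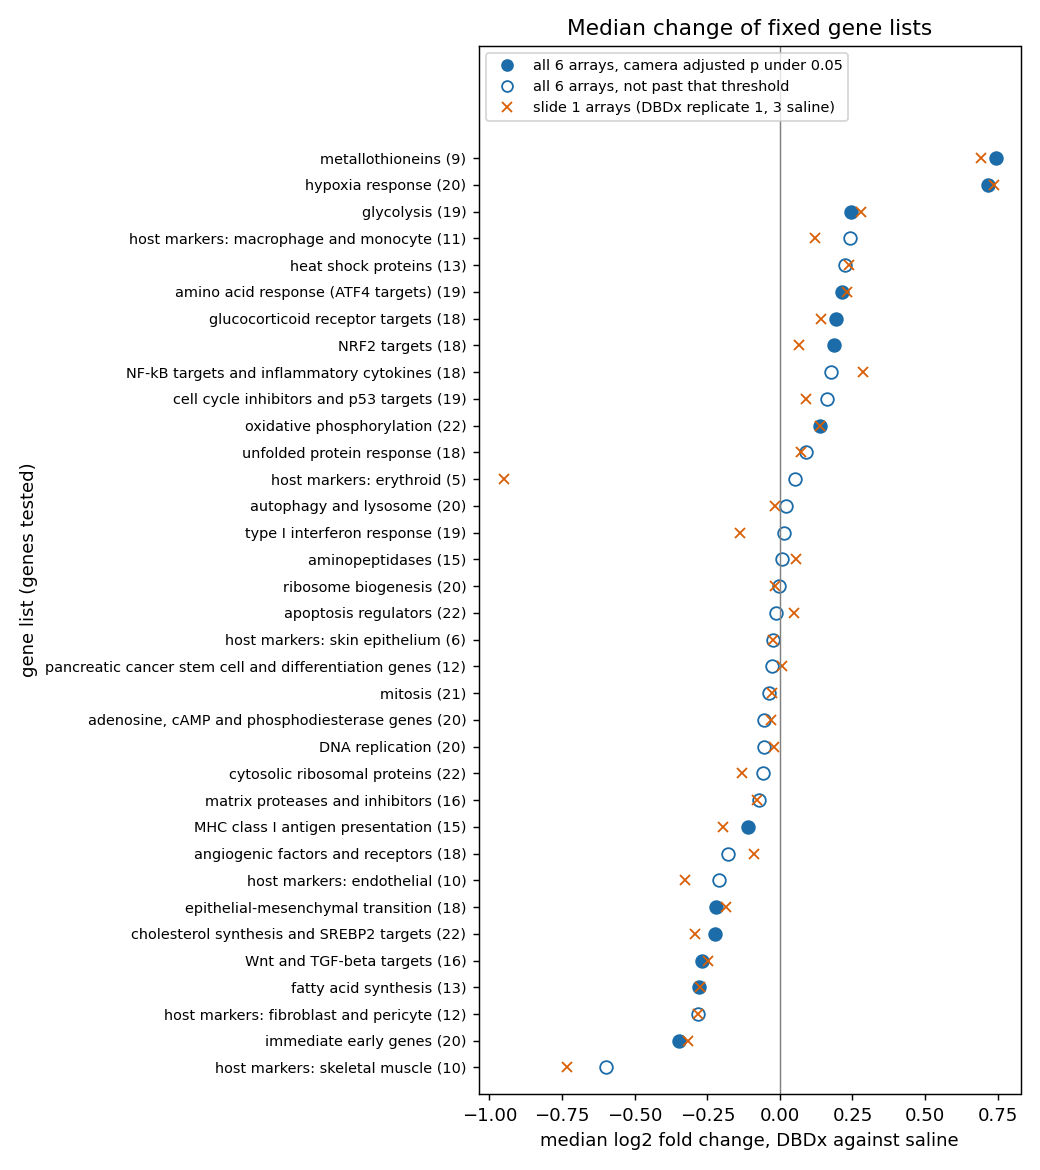
Median log2 fold change (horizontal axis, DBDx against saline) of 35 of the 36 gene lists tested, with the number of genes tested in brackets. Filled circles mark the 13 lists past an adjusted p of 0.05 with camera at the preset correlation, open circles the others, and crosses the median inside slide 1. Metallothioneins (0.74) and the hypoxia response (0.72) have the highest medians, on slide 1 alone 0.69 and 0.74.

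No cell division list passed in the main comparison. None of 21 mitosis genes and none of 20 DNA replication genes was past the threshold, over all genes or adjusted over the list alone (medians -0.04 and -0.05, camera adjusted p = 0.520 and 0.281). With host markers as a covariate the mitosis list passed, down (adjusted p = 0.00457). MKI67, which encodes the proliferation antigen Ki-67, had a log2 change of -0.42 ± 0.08 SE (adjusted p = 0.0844), and its 3 probes ranged from -0.42 to 0.11. None of 22 apoptosis regulators passed either way (camera adjusted p = 0.749; their median was -0.01 and their mean 0.02), and none of 19 cell cycle inhibitors and p53 targets passed over all genes, while 1 fell when adjusted over the list alone (camera adjusted p = 0.581). CDKN1A, the cyclin-dependent kinase inhibitor p21, and MYC had log2 changes of 0.16 ± 0.27 and -0.14 ± 0.14 (adjusted p = 0.768 and 0.623). Cytosolic ribosomal proteins (camera adjusted p = 0.520) and ribosome biogenesis (0.996) were not past the threshold as sets, and none of their genes passed either way.

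The lists around the presumed targets of dipyridamole and ubenimex did not pass. Among 20 adenosine, cAMP and phosphodiesterase genes none passed over all genes and 1 rose when adjusted over the list alone (PDE10A, log2 change 0.67, adjusted p = 0.0694 over all genes), with a camera adjusted p = 0.538. PDE5A, a phosphodiesterase that dipyridamole inhibits, had a log2 change of 0.48 ± 0.47 SE and SLC29A1, the nucleoside transporter that dipyridamole blocks, one of -0.08 ± 0.10 (adjusted p = 0.602 and 0.671). None of 15 aminopeptidases passed (camera adjusted p = 0.787). LTA4H, an aminopeptidase inhibited by bestatin, had a log2 change of 0.03 ± 0.08 (adjusted p = 0.840), and ANPEP, aminopeptidase N, was below the filter on dim probes. A p that misses the threshold does not show that these genes stayed level.

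Several stress and inflammatory lists held single genes that rose without the list passing. DDIT3, a transcription factor of the unfolded protein response, was 2.86-fold higher (adjusted p = 0.0203) while its list, with 2 higher when adjusted over the list alone, had a camera adjusted p = 0.261. CCL20, a chemokine not well above background on any saline array, was at least 2.37-fold higher (adjusted p = 0.0347) in the NF-kB list, which had 2 higher when adjusted over the list alone, with a camera adjusted p = 0.122 that became 0.0432 with slide as a block, 0.00446 without saline replicate 2 and 0.043 without DBDx replicate 2. MAP1LC3B, an autophagosome protein, was 2.05-fold higher (adjusted p = 0.0460) and CXCR4, a chemokine receptor, 1.72-fold higher (adjusted p = 0.0412), each the only gene past the threshold in its list (autophagy and lysosome, camera adjusted p = 0.642; pancreatic stem cell and differentiation genes, 0.561). Adjusted over the list alone, 1 and 3 genes of these lists rose. The angiogenesis list had 2 higher genes, ANGPTL4 and VEGFA, and a camera adjusted p = 0.996, with a median of -0.18 and a mean of 0.12; 4 rose and 1 fell when adjusted over the list alone. The fixed lists of heat shock proteins, which does not hold HSPA6, of type I interferon response genes, and of matrix proteases and inhibitors had no gene past the threshold over all genes and camera adjusted p of 0.122, 0.839 and 0.538. Adjusted over the list alone, 2 interferon response genes rose and 1 fell, 1 gene of the matrix list fell, and none of the heat shock list passed. The heat shock list passed, up, without saline replicate 2 and without DBDx replicate 2 (adjusted p = 0.0176 and 0.0373).

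Transcripts of host cells are of the mouse and are seen by these human probes only where they bind across species. The signal of a marker can also come from the human tumour cells, and its source was not tested. Fibroblast and pericyte markers had a median log2 change of -0.28 (camera adjusted p = 0.0617; -0.28 inside slide 1) and endothelial markers one of -0.21 (0.120; -0.33 inside slide 1), with no gene past the threshold over all genes in either and 1 endothelial gene lower when adjusted over the list alone. The fibroblast list passed with camera, down, with an intensity trend and robust variance (adjusted p = 0.04), without saline replicate 2 (0.0192) and without DBDx replicate 3 (0.0269). The endothelial median of -0.33 inside slide 1 rests on 1 DBDx tumour. Among 11 macrophage and monocyte markers CD68 was 1.88-fold higher (adjusted p = 0.0462) and none was lower, or 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.548), and C1QB had a log2 change of -0.83 (adjusted p = 0.0841). LCN2, 1 of 4 tested neutrophil markers, was 2.45-fold higher (adjusted p = 0.0176), and 2 of the 4 rose when adjusted over the list alone; that list and the adipocyte list had under 5 tested genes and got no set test. Erythroid markers, with a median of 0.05 but a mean of -0.57, had a camera adjusted p = 0.389, and 2 of 5 fell when adjusted over the list alone. They passed, down, with slide as a block. Inside slide 1, with 1 DBDx tumour, their median was -0.95. The haemoglobin gene HBA2 had a log2 change of -1.85 ± 0.30 SE (adjusted p = 0.0549), and its 3 probes ranged from -1.92 to -0.41. Skeletal muscle and skin markers did not pass (camera adjusted p = 0.261 and 0.938), with 1 muscle gene higher when adjusted over the list alone; the muscle list passed, down, without saline replicate 2 (0.0153) and with a replicate block (0.0451). With the mean of the fibroblast, endothelial and macrophage markers as a covariate, 1 gene and 10 lists passed, and the calls of the glucocorticoid receptor, ATF4, oxidative phosphorylation and NRF2 lists ended (adjusted p = 0.791, 0.791, 0.360 and 0.280).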

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

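Leaving out 1 array gave between 0 and 1634 changed genes, between 0 and 782 higher, between 0 and 852 lower, and between 7 and 15 lists, against 255, 151, 104 and 13. The 1634 genes came without DBDx replicate 1, where slide and treatment coincide. Counts were 520 (274 higher, 246 lower) with normexp, 431 (246 and 185) with an intensity trend and robust variance, 42 (29 and 13) without a filter, where 27708 genes were tested, 60 (11 and 49) with the slide block, and 1 (1 and 0) with host markers as a covariate. Other thresholds gave 832 (477 and 355) at an adjusted p under 0.1, 687 (235 and 452) at an unadjusted p under 0.05 with at least 2-fold, and 128 (75 and 53) at an adjusted p under 0.05 with at least 2-fold. Of alternatives chosen after seeing the data, the slide block with saline replicate 3 left out gave 0 genes (0 and 0; 1595 at an unadjusted p under 0.05 with limma) and the slide 1 arrays only gave 0 (0 and 0; 2773). Quantile normalization, median scaling, the deposited values, the filter on all 6 arrays, both other uses of probes, array weights and genes with a symbol gave between 256 and 327. Array weights, whose estimation stopped before its convergence tolerance, gave 7 lists, an estimated correlation 0, mixed fry 28 and directional fry 9. With directional fry the cholesterol, ATF4 and immediate early lists did not pass (adjusted p = 0.123, 0.123 and 0.133). Nor did the oxidative phosphorylation and MHC class I lists (adjusted p = 0.0817 and 0.0888). Its 9 lists include the angiogenesis list, which camera did not pass, at an adjusted p that rounds to 0.05. With the replicate block 0 genes passed (0 higher, 0 lower; 3053 at an unadjusted p under 0.05, smallest adjusted p = 0.0971) and 13 lists. Same-numbered arrays did not deviate together (correlations across genes 0.0014, -0.028 and -0.083), and not each array correlated best with its own number. These values give no sign that the numbers pair the tumours, but with 3 arrays per group they cannot exclude it. No named gene or list past the threshold changed direction under an alternative that could show it. Their calls held in 523 of 1045 gene results and 265 of 325 list results. The run on every probe followed only the brightest probe of a named gene, and mixed fry gives no direction. Other kept probes of HLA-DQB1 and BCL11B reached the opposite sign (log2 changes up to 0.271 and 0.481). Fewer arrays leave fewer degrees of freedom; otherwise the cause of these differences was not tested. Where a probe was not well above background on any array of a group, only a bound on its fold change can be given.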

Other observations

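The tests on MHC class II, leukocyte and clock genes used lists written after some of their genes had been seen, and the tests of the array splits for genes, of saline replicate 3 as an independent array, of a mixture and of leukocytes were chosen only after the result was seen. Of 10 tested MHC class II genes, CD74 and CIITA included, 4 fell and none rose: HLA-DPB1, HLA-DQB1, HLA-DRB1 and CD74. HLA-DMA, which loads peptides onto class II molecules, had a log2 change of -0.98 ± 0.21 SE and did not pass (adjusted p = 0.0898). HLA-DPA1 and HLA-DQA1, at lower signals, had log2 changes of 0.17 and 0.21 and did not pass (adjusted p = 0.615 and 0.587). HLA-DMB and HLA-DOA were well above background on the 3 DBDx arrays only and did not pass (adjusted p = 0.471 and 0.314), and HLA-DRA was below the filter.

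Further genes, chosen after their values were seen, also passed. PER2 and PER3, repressors of the clock, fell by 0.85 and 0.84 on the log2 scale (adjusted p = 0.0325 and 0.0488), and NFIL3, a repressor of clock output, was 2.30-fold higher (adjusted p = 0.0158). The acute phase protein SAA1 was 3.17-fold higher (adjusted p = 0.0235) and the complement receptor C3AR1 3.16-fold higher (adjusted p = 0.0295). A candidate explanation for the clock genes is another clock phase at harvest. The median log2 change of 4 tested clock output genes was -0.123 (SD over array pairs 0.162) and that of BMAL1, CLOCK, NPAS2 and CRY1 0.02 (SD 0.144); both lie within the 0.2 of 0 set beforehand against this explanation, but the first not by more than its spread, and TEF (-1.34) and NR1D1 (0.42) went apart. That a value must clear its bound by its spread was applied to this test and to that of CIITA after the values were seen; so read, the test leaves this open.

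Saline replicate 3 lay between saline replicates 1 and 2. Mixed RNA or cRNA of the other 2 saline tumours may be the cause: 1 linear mixture left a residual 0.928 times the noise between spots, and the 11 gene lists with at least 5 genes far enough apart gave weights between 0.573 and 0.667. Lists with fewer such genes reached down to 0.458 (MHC class I, 1 gene). Of 11675 genes 194 (1.66%) lay more than 0.3 off the mixture, 159 of them above it, so the values used here are not exactly this average of the other 2 arrays. An average computed in another way was not tested. A tumour state graded on the log scale in all genes should leave log2 interpolation a residual no larger than that of linear mixing. The residual was 1.17 times as large, over only 14 genes at least 4-fold apart, which does not decide between them. A tumour whose intermediate state mixes signals linearly cannot be told from mixed RNA by this test. The sources used here do not say whether RNA was pooled.

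The 255 changed genes were set against 3 technical readings. No other of the 10 splits of the 6 arrays gave a changed gene (real count 255, highest other 0, 1 split as large), but 10 splits are too few for a share under 0.05. For the lists, 3 of the 10 splits gave as many (real count 13, highest other 16), so a count of this size also came from splits that mix the groups. A slide difference may account for part of the pattern: genes at least 2-fold apart between slide 2 and 1 saline array had the same sign inside slide 1, against another saline array, in 57.1% (saline replicate 1 used to pick, 2 to look) and 68.3% (the reverse). The 4 choices that use saline replicate 3, which is no separate array if it is a mixture, gave between 60.9% and 74.3%. In the first choice rises kept their sign in 70% and falls in 53.6%. At most 60% had been set for a slide effect alone and at least 75% against it, so this test does not decide. Whether the calls rest on saline replicate 3 counted as independent was not decided. Without it 0 genes passed in a design with fewer arrays, and 4 of the other 5 arrays also left under 128 genes when removed. The called genes kept their folds without it (median ratio 0.999), which an array lying between the other saline arrays would also give. Treatment stays among the open explanations.

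The fall of HLA-DPB1, HLA-DQB1, HLA-DRB1 and CD74 has no settled explanation. A loss of leukocytes from DBDx tumours could lower them, and should then lower other leukocyte genes alike. The median log2 change of 14 tested leukocyte genes was -0.0138 (SD over array pairs 0.168), with CXCR4 the only gene past the threshold, and 5 of the 22 listed genes are in other lists. Of the 14 estimates 8 were negative; CD79A, PTPRC and FCER1G, among the brighter of them, had log2 changes of -0.45 ± 0.20, 1.29 ± 0.49 and 0.16 ± 0.29, and the largest fall was that of CD37 (-1.06 ± 0.31, adjusted p = 0.153). Of 7 leukocyte genes outside that list, named after their values were seen, 2 fell past the threshold (MNDA, at least 4.76-fold, and BCL11B, 6.09-fold) and 3 rose past it (CD68, LCN2 and C3AR1, 1.88-fold, 2.45-fold and 3.16-fold). C1QB and ITGAM had log2 changes of -0.83 and -0.70 and did not pass (adjusted p = 0.0841 and 0.220). These genes go apart, host leukocytes are of the mouse, and which human probes bind their transcripts was not tested. The human probes also read the human tumour cells, and which cells gave these signals was not tested. A loss of leukocytes therefore stays open. What would count against it was reworded after the values were seen. A fall of CIITA, the transactivator of MHC class II genes, may be the cause, but its log2 change was -0.403 ± 0.19 SE. This is under the 0.5 set beforehand against this explanation, though not by 2 SE, so it leaves the matter open; treatment of the tumour cells remains open as well.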
